A study of Homo sapiens with 9 samples.

How the data were processed

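Gene expression was measured by RNA sequencing in 9 libraries of NB4 cells. Groups were taken from the sample labels: DMSO, MC_2580, RA 0.01 uM, RA 1 uM and MC_2580 + RA 0.01 uM, each 24 h and 1 library, and LSD1 KO and WT, 2 libraries each. The labels give no dose for MC_2580.

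Per the file headers and the values, the expression values the authors deposited in both tables are FPKM in the layout of Cuffdiff. In the knockout table the authors added 0.001 FPKM to every value, which was taken off. The submitters' processing notes name CASAVA 1.8, TopHat 1.3.1, TopHat2 2.0.10, Cufflinks, Cuffdiff and genome build hg18, without a role or an order, and do not state the annotation or the scaling between libraries. The deposited fold changes are log2 ratios of KO over WT in the knockout table and natural log ratios in the treatment table, as recomputed from the deposited FPKM values. Per the file headers, both deposited tables also hold a p-value and a q-value from the authors' tests of 1 library against another. The deposited q-values reach 1.44 in the treatment table, so they are not bounded as probabilities are, and they were used only through the authors' significance calls.

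There are 36119 genes in the knockout table and 35856 in that of the treatments, the latter for all 10 pairs of 5 libraries. Values of tests with a failed status, all listed at 0, were treated as missing, which left 1039 treatment genes with at least 1 missing library. The knockout table has 7 genes with a failed status and 1 with too many fragments. Another 202 treatment values were listed at 0 in some pairs only, and the value above 0 was used. Symbols were matched to RefSeq gene names and their synonyms, 23021 in the knockout table and 23026 in the treatment table. Of these 16943 and 16956 were protein-coding genes with 1 locus. KDM1A is listed as AOF2. Locus lengths at 562 miRNA loci equalled end minus start in 49.1% and end minus start plus 1 in 0%, so starts count from 0 and 1 was added to them. Total reads per library were not given, so no counting interval was computed; relative depth was read from the spacing of low values.

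KO and WT were compared with limma 3.58.1 (trend) in R 4.3.3 on log2(FPKM + 1), for genes with a group mean of at least 1 FPKM, with Benjamini-Hochberg adjusted p at 0.05. The 19 gene lists (461 entries, 432 and 434 matched in the tables) were chosen before the data were examined and tested with limma's camera (preset correlation 0.01, then estimated) and fry, adjusted over the lists. Where a library was left out, the lone library of its group was assumed to vary like the other group. Counts of list members adjusted over the list alone are given too. For the treatments, log2((value + 1)/(control + 1)) was computed for genes of at least 1 FPKM in 1 of the libraries compared, and a gene was called higher or lower at 2-fold. List medians were set against 10000 random lists matched on 10 expression groups, and percentiles are given for lists with at least 3 members. The deviation of the combination from the sum is its log2 difference minus those of MC_2580 and RA 0.01 uM. For the shared DMSO library, 100 simulations of unchanged libraries drew noise from the differences between replicates in the knockout table, which gave 163.51 higher protein-coding genes at 2-fold where MC_2580 had 68. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

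The genes named were set by a rule written before the data were examined: KDM1A, the 10 largest rises and 10 largest falls past the threshold with no overlap between replicates, the 10 highest and 10 lowest per treatment comparison and against the sum among genes of at least 5 FPKM in 1 library, and list members as examples. The same rule within protein-coding genes with 1 locus was added after the data were seen. Alternatives tried were other pseudocounts and filters, quantile normalization, a replicate block, leaving out each library, a 4-fold threshold, rescaling to a median of 0, a linear sum, and the authors' calls; the restriction to protein-coding genes was chosen after the data were seen. On simulated data with 50 changed genes per size, limma recovered 0 at 2-fold, 29 at 4-fold, 43 at 16-fold and 41 at 64-fold among 13157 loci with 10 false calls, and 18, 47, 50 and 50 among 9762 protein-coding genes with 11. For the treatments 200 of 200 genes changed 8-fold were recovered with 0 false calls, which checks the computation and not the error rate, since the simulated noise lay well below 2-fold. Between libraries of 1 group in the knockout table the same rule marked 3.4% to 3.8% of protein-coding genes.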

Results

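Gene expression was measured by RNA sequencing in NB4 cells, an established human acute promyelocytic leukaemia line that carries the PML-RARA fusion and matures along the granulocyte path under retinoic acid (RA). The 9 libraries form 2 sets. In the treatment set, 1 library each came from cells kept for 24 h in DMSO, in MC_2580 (labelled only as an inhibitor of the histone demethylase LSD1), in RA at 0.01 uM, in RA at 1 uM, or in MC_2580 with RA at 0.01 uM, called the combination here. The knockout set holds 2 libraries of LSD1 knockout (KO) cells and 2 of wild-type (WT) cells. Values are FPKM, 36119 loci in the knockout table and 35856 in the treatment table. At least 1 FPKM was reached by 11974 to 13365 loci per library, and the 10 highest loci held 50.5% to 65.7% of each library's FPKM sum. Read totals are not given in the sources used here. From the spacing of low values, 1 FPKM corresponded to 1.04, 1.35 and 1.66 times as many reads in KO 1, KO 2 and WT 2 as in WT 1, and to 0.89, 0.73, 0.90 and 0.77 times as many in the MC_2580, RA 0.01 uM, RA 1 uM and combination libraries as in DMSO. The labels do not say that the replicates are separate cultures, so p-values measure only the spread between these samples.

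The comparison of KO with WT cells asks what loss of LSD1 does in untreated NB4 cells. The labels do not say how many KO clones the libraries came from. For all genes below, other differences between the lines therefore cannot be told apart from loss of LSD1. KDM1A, the gene for LSD1 (AOF2 in the table, chromosome 1, 23218533 to 23282771, build hg18), stood at 14.0 and 16.8 FPKM in the KO libraries against 49.8 and 66.6 in WT. All KO values lay below all WT values, a log2 difference of -1.84 (SE 0.23), which missed the threshold among all loci (limma adjusted p = 0.158). Of 13157 loci tested, 15 passed an adjusted p of 0.05 in limma, 8 higher and 7 lower in KO cells, and 942 had an unadjusted p under 0.05. Without any difference a share of 0.05 of the loci would reach that unadjusted level. Only 4 of the 15 were protein-coding genes. The other 11 were short RNA or unnamed loci listed at 0 in both libraries of 1 group, among them MIR942 (hsa-mir-942, 35.9 and 27.6 FPKM in KO) and MIR646 (hsa-mir-646, 23.1 and 17.8 in KO), and their values came in ratios that 1 to 4 reads give.

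CLEC5A, a myeloid C-type lectin receptor (chromosome 7, 141273626 to 141293252), rose from 1.24 ± 0.0233 to 26.5 ± 2.85 FPKM (SD, n = 2 per group), with a log2 change of 3.61 (SE 0.16, limma adjusted p = 0.0453). RTN4RL2, a Nogo receptor family member (chromosome 11, 56984893 to 57001005), rose from 1.41 ± 0.123 to 24.1 ± 2.86 FPKM (3.37, SE 0.17, limma adjusted p = 0.0496). PXDN, the extracellular matrix peroxidase peroxidasin (chromosome 2, 1614666 to 1727298), fell from 14.1 ± 1.88 to 0.0235 ± 0.0129 FPKM, a log2 change of -3.87 (SE 0.20, limma adjusted p = 0.0496). DEFB1, a beta-defensin (chromosome 8, 6715511 to 6722939), fell from 38.2 ± 0.765 to 3.67 ± 0.451 FPKM (-3.07, SE 0.16, limma adjusted p = 0.0496). Without any 1 of the 4 libraries limma called 0 loci, with 654 to 801 at an unadjusted p under 0.05. The authors' deposited table, which tests each KO library against the WT library of its number, calls 117 loci for replicate 1 and 96 for replicate 2, of which 60 are shared (40 higher, 20 lower).

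An alternative chosen after the data were seen kept only protein-coding genes with 1 locus, which removes the short loci. Of 9762 such genes 59 passed in limma, 43 up and 16 down, and all 4 genes above were among them. The 10 largest rises in that fit were in CT45A5, a cancer/testis antigen (19.2 and 25.1 FPKM in KO, 0.64 and 0.62 in WT), CLEC5A, RTN4RL2, ITM2A (66.3 and 50.6 against 4.70 and 5.32), S100A9 (39.9 and 55.9 against 4.30 and 3.84), TMEM243 (C7orf23 in the table, 30.8 and 19.6 against 1.91 and 1.5), CKAP4, IGSF3, S100A8 (10.3 and 17.4 against 0.63 and 1.23) and SLC18B1 (C6orf192 in the table, 7.29 and 6.27 against 0.08 and 0.05). S100A8 and S100A9 encode the subunits of calprotectin, a protein of maturing myeloid cells. The largest falls were in PXDN, DEFB1, PRG2, which encodes eosinophil major basic protein (175 and 217 against 1517 and 1713), KCNH2, a potassium channel (1.25 and 1.90 against 15.1 and 23.0), EPCAM (1.73 and 0.73 against 11 and 12.9), GAPT, SDC2 and BMP2, and in RAB3C and EMC10 (C19orf63 in the table), both listed at 0 in the KO libraries. In this fit limma's adjusted p for KDM1A (AOF2) was 0.0575.

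**Figure D1:**
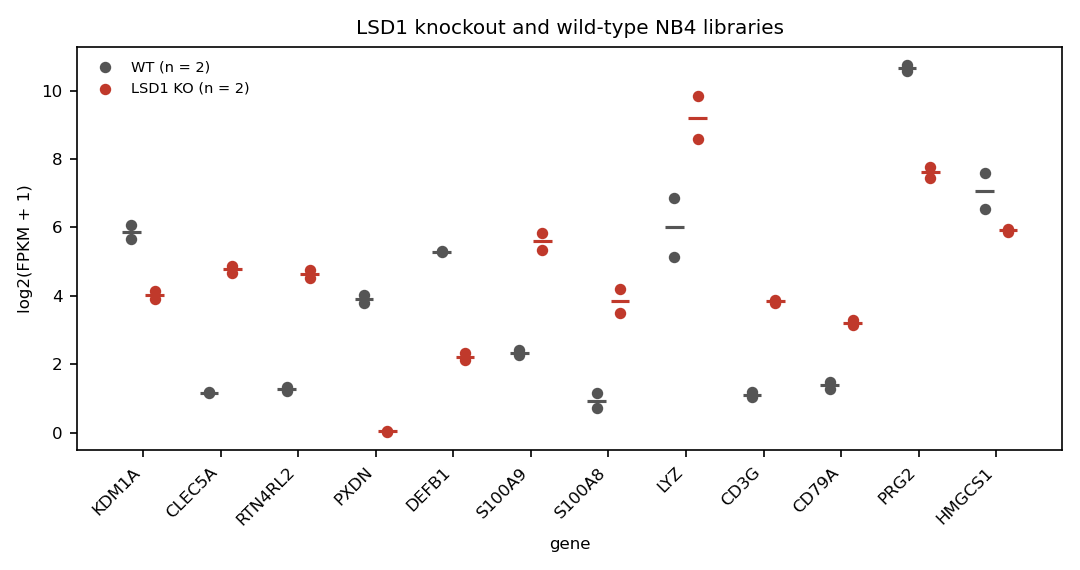
FPKM of 12 genes in KO and WT libraries, on a log2(FPKM + 1) axis; each point is a library and each bar the mean of a group's 2 libraries on that scale. CLEC5A, RTN4RL2, PXDN and DEFB1 passed the test among all loci; KDM1A, LYZ and HMGCS1 passed in neither fit, while S100A8, S100A9, CD3G, CD79A and PRG2 passed only among protein-coding genes.

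Genes of cholesterol synthesis were lower in KO cells as a list: 18 of 20 members lay below WT, with a median log2 difference of -0.66 (limma camera adjusted p = 7.59e-07 with the preset correlation, adjusted p = 0.688 with an estimated correlation). The median was -0.32 without WT 1 and -1.05 without WT 2. In the limma fit without pairing by replicate number no single member passed, and 0 passed adjusted over the list alone. HMGCS1, which makes HMG-CoA for the pathway, stood at 60.8 and 57.9 FPKM against 191 and 92.1, and LSS, the lanosterol synthase, at 10.4 and 10.6 against 23.7 and 19.6. Chemokine and NF-kB genes had a median of -0.51 (camera adjusted p = 0.0389, adjusted p = 0.688 with an estimated correlation). Adjusted over the list alone 1 of these 17 rose, IL1RN, the interleukin 1 receptor antagonist (22.1 and 21.6 against 5.03 and 2.86), and 1 fell, CCL2 (0.17 and 0.13 against 3.44 and 3.0). Without KO 2 or without WT 1 the median of the chemokine and NF-kB list turned positive, 0.06 and 0.07. It was -0.88 without KO 1 and -0.95 without WT 2. Replicate 1 lay above replicate 2 for this list in both groups (median 0.99 in WT and 0.73 in KO). Leaving out 1 library unbalances that difference.

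Markers of other cell types moved in both directions. The lymphoid list was higher in KO cells (9 tested members, median 0.87, camera adjusted p = 3.95e-05, adjusted p = 0.688 with an estimated correlation). Adjusted over the list alone 3 members rose and 0 fell: CD3G, a T-cell receptor chain (12.9 and 13.6 against 1.28 and 1.05), CD2 (3.45 and 3.06 against 0.07 and 0.06) and CD79A, a B-cell receptor chain (7.87 and 8.77 against 1.79 and 1.43). Without WT 2 the median of the lymphoid list was 0.57. WT cells themselves held 7 of the 9 at 1 FPKM or more, CD3D at 115 and 69.0. The 4 fibroblast and epithelial genes tested were lower (median -0.71, camera adjusted p = 0.0389, adjusted p = 0.688 with an estimated correlation), among them EPCAM and SPARC (13.5 and 18.2 against 22.3 and 30.3), while VIM had a log2 difference of 0.20; this call was lost without KO 2 and without WT 1. Of 5 eosinophil, basophil and mast cell genes, with a median of -0.36 (camera adjusted p = 0.179), PRG2 and EPX, the eosinophil peroxidase (2.00 and 2.35 against 11.7 and 20.1), fell adjusted over the list alone, and IL5RA rose (2.85 and 1.60 against 0.06 and 0.05).

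Among 29 granulocyte maturation genes the median was 0.17 (camera adjusted p = 0.133). Adjusted over the list alone 4 rose and 0 fell: S100A9, S100A8, C5AR1, the complement C5a receptor (4.13 and 3.60 against 0.82 and 1.10), and CEBPE, a transcription factor of late granulocyte differentiation (75.2 and 69.4 against 34.5 and 39.5). LYZ, the lysozyme gene, stood at 381 and 912 against 34.1 and 116 FPKM, but its replicates differed widely and it did not pass (log2 difference 3.21, SE 0.79, limma adjusted p = 0.507). In both groups replicate 2 was the higher, and the authors' tests called LYZ higher in KO for both replicate numbers. The labels do not say what a number marks. Of 12 monocyte and macrophage genes (median 0.40, camera adjusted p = 0.0614) TREM1 alone rose adjusted over the list alone (12.4 and 9.54 against 2.65 and 3.62). In the list of LSD1 complex members (21 genes, median 0.10, camera adjusted p = 0.389) GFI1, a repressor that recruits LSD1, rose (98.4 and 98.2 against 43.7 and 46.5) and KDM1A (AOF2) fell, adjusted over the list alone. Of 9 haemostasis genes (median 0.47, camera adjusted p = 0.0614) ANXA2 rose (223 and 293 against 98.1 and 121) and F3, tissue factor, fell (4.90 and 4.34 against 8.89 and 11.6) by the same adjustment, as did DEFA4 among 16 primary granule genes (0 and 0.14 against 3.03 and 3.31; list median 0.28 but mean -0.02, camera adjusted p = 0.363) and the receptor kinase gene RET among 11 retinoid genes (6.18 and 6.77 against 20.6 and 21.3; median -0.15, camera adjusted p = 0.318). No member passed over its list alone for interferon response (median -0.24, camera adjusted p = 0.264), cell cycle (-0.17, 0.146), CDK inhibitors and growth arrest (-0.13, 0.701), MYC targets and ribosome biogenesis (-0.12, 0.389), apoptosis and stress (-0.02, 0.706), stem and progenitor (0.06, 0.744), erythroid (0.44, 0.179) or megakaryocyte genes (-0.13, 0.848). By fry, which tests each list on its own, the eosinophil, basophil and mast list passed (adjusted p = 0.0382) and without any 1 of the 4 libraries fry called 0 lists, while camera with the preset correlation called 4 to 7. Cell cycle genes had a median of -0.47 without KO 2 and -0.31 without WT 1, but 0.16 without KO 1 and 0.10 without WT 2. MYC targets had -0.42 without KO 2 and -0.47 without WT 1, but 0.14 without KO 1 and 0.16 without WT 2. Interferon genes had -0.62 without WT 2 but 0.21 without WT 1. Monocyte and macrophage genes had 0.49 without KO 2, 0.72 without WT 1, 0.20 without KO 1 and 0.18 without WT 2. Haemostasis genes had 0.49, 0.73, 0.47 and 0.21 in that order, and erythroid genes had 0.54 without WT 1. In the fit over protein-coding genes camera called the monocyte and macrophage list and the haemostasis list (adjusted p = 0.0499 for both). Replicate 1 differed from replicate 2 in the same direction within both groups for several lists. That median log2 difference was -0.41 in WT and -0.64 in KO for cell cycle genes. It was -0.61 and -0.66 for MYC targets, and 0.79 and 0.26 for interferon genes. Leaving out 1 library unbalances this difference, so the medians without 1 library carry it too. With an estimated correlation camera called 0 lists in every setting. Counts adjusted over the list alone also changed without 1 library. For granulocyte maturation genes they were 3 risen without KO 1 and 0 without each of the other 3 libraries. For the LSD1 complex, haemostasis and retinoid lists they were 0 in all 4 cases. They were 0 for chemokine and NF-kB genes except without WT 1, and 0 for monocyte and macrophage genes except without KO 2. For primary granule genes 2 fell without WT 1 and 0 without each other library, and for lymphoid genes 5 rose and 1 fell without WT 1. For eosinophil, basophil and mast genes 2 rose and 3 fell without WT 1 and 0 rose without WT 2.

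All treatment comparisons set 1 library against another. They have no replicate check and no p-value, and a gene is called higher or lower here by size alone, 2-fold on the FPKM + 1 scale. Between libraries of a single group in the knockout table that rule marks 366 of 9653 protein-coding genes (3.8%) for WT 1 against WT 2 and 333 of 9770 (3.4%) for KO 1 against KO 2. Over all loci it marks 1158 of 12783 (9.1%) and 1112 of 12950 (8.6%). Against DMSO it marks 3.9% of all loci and 0.8% of protein-coding genes for MC_2580, 9.4% and 7.7% for RA 0.01 uM, 10.7% and 9.2% for RA 1 uM, and 13.7% and 12.8% for the combination. For the combination against RA 0.01 uM the shares are 7.0% and 5.0%. Counts over all loci alone do not set that comparison, MC_2580 or RA 0.01 uM apart from differences within a group of the knockout table, which is another set. For gene lists, 85 of 127 medians over these comparisons and the sum lay in the lowest or highest 2.5% of matched random lists, but so did 8 of 18 for WT 1 against WT 2 and 7 of 18 for KO 1 against KO 2, a comparison added after the data were seen. A percentile therefore does not set a list apart from differences between like libraries. In that order those medians were 0.99 and 0.73 for chemokine and NF-kB genes, 0.79 and 0.26 for interferon genes, 0.65 and 0.07 for cholesterol synthesis, -0.61 and -0.66 for MYC targets, -0.41 and -0.64 for cell cycle genes, 0.50 and 0.39 for monocyte and macrophage genes, 0.44 and 0.49 for retinoid genes and 0.16 and 0.14 for granulocyte maturation genes. In size the medians of MYC targets, cell cycle, cholesterol synthesis, megakaryocyte and fibroblast and epithelial genes stayed within the larger same-group value in all 6 treatment comparisons. Those of the monocyte, granulocyte maturation, haemostasis, primary granule and eosinophil, basophil and mast lists lay beyond it in all 6. Some margins were narrow. The eosinophil, basophil and mast list had -0.183 for the combination against RA 0.01 uM and -0.176 between WT 1 and WT 2. In the same comparison the primary granule median was -0.172 without DEFA1 and DEFA3, against -0.191 between WT 1 and WT 2. Short RNA loci at 0 in 1 library fill the ends of the ranked lists: of the 140 loci that the rule for named genes selects over the treatment comparisons, 112 are snoRNA, scaRNA or miRNA loci and 22 are protein-coding. The genes named below follow the same rule within protein-coding genes with 1 locus, a restriction chosen after the data were seen, or belong to the lists set beforehand.

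MC_2580 alone was set against DMSO to ask what inhibition of LSD1 does without RA. The largest differences were in CXCL10, an interferon-induced chemokine (1.84 FPKM in DMSO and 20 with MC_2580, but also 12.7 and 1.68 in the WT libraries and 6.14 and 1.55 in the KO libraries), TMEM243 (C7orf23 in the table, 1.95 and 17.6), LYZ (45.3 and 289.7), S100A9 (2.44 and 17.1) and ITGAM, the CD11b integrin chain of mature myeloid cells (2.68 and 13.9). FUT7, ART3, IL1RN (3.35 and 14.5), RTN4RL2 (2.69 and 11.8) and ICAM4 completed the 10 highest. Of these 10, 5 differed 2-fold between libraries of 1 group in the knockout table, CXCL10, LYZ, ITGAM, ART3 and ICAM4, though 0 by as much as with MC_2580. The lowest protein-coding genes differed little, DEFA3 (21.2 and 10.2, shared reads with DEFA1 making it uncertain), MUTYH (15.3 and 7.24), EGR1 (24.9 and 13.8, but 11.8 and 3.26 in the WT libraries) and ASNS (71.4 and 42.3) among them. Of 13449 loci 298 were higher and 233 lower, and of 9385 protein-coding genes 70 were higher and 1 lower, fewer than between libraries of 1 group in the other table. KDM1A (AOF2) was at 69.9 FPKM in DMSO and 66.9 with the inhibitor.

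With MC_2580, 12 of 18 list medians lay in the lowest or highest 2.5%, and 7 of these 12 were larger than between libraries of 1 group, which leaves out the chemokine, interferon, cholesterol synthesis, MYC target and retinoid lists. Granulocyte maturation genes had a median log2 difference of 0.46 (percentile 100; 4 of 24 higher, 0 lower), monocyte and macrophage genes 0.53 (percentile 100; 5 of 12 higher), chemokine and NF-kB genes 0.55 (percentile 100; 3 of 17 higher) and interferon genes 0.28 (percentile 99.99; 0 of 21 higher). Examples were KLF4, a monocyte transcription factor (1.58 and 5.58), LY96 (0.25 and 4.06), IRF8 (6.32 and 16.3), ICAM1 (10.6 and 28.7) and S100A8 (0.92 and 4.71). Haemostasis genes had 0.38 (percentile 99.94), with ANXA2 at 31.9 and 76.6, and CDK inhibitors 0.23 (percentile 99.94). Medians lay low for cholesterol synthesis (-0.22, percentile 0; HMGCS1 406 and 286) and for apoptosis and stress (-0.17, percentile 0; TRIB3 121 and 87.6), with 0 members 2-fold lower in either, and for MYC targets (-0.11, percentile 1.19). Cell cycle genes had -0.08 (percentile 5.82), stem and progenitor genes 0.05 (86.43), LSD1 complex genes 0.01 (73.74), lymphoid genes 0.20 (95.66), eosinophil, basophil and mast genes 0.26 (99.16), retinoid genes 0.25 (99.47), primary granule genes 0.25 (100; 0 of 17 higher, 1 lower, mean 0.05), fibroblast and epithelial genes 0.17 (90.21) and megakaryocyte genes -0.01 (52.45).

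RA at 0.01 uM and at 1 uM was set against DMSO to describe the response at a low dose and at a higher one. The highest protein-coding genes at both doses included NCF1, FGR and S100A9 of the granulocyte maturation list, CCL2 of the chemokine list, and ALOX5AP. NCF1, a subunit of the phagocyte NADPH oxidase, was at 2.72 FPKM in DMSO, 929 at 0.01 uM and 1305 at 1 uM, although it shares reads with its pseudogenes and is uncertain. ALOX5AP, needed for leukotriene synthesis, was at 2.81, 773 and 808, CCL2 at 2.12, 385 and 854, S100A9 at 2.44, 369 and 430.1, and the kinase gene FGR at 0.69, 158 and 256. The lowest genes at 0.01 uM were VIM, which encodes the intermediate filament vimentin (593, 22.2 and 42.7), CYTL1 (201, 7.71 and 9.03), STAB1 (12.5, 0.19 and 0.27), HDC, the histidine decarboxylase (58.4, 6.27 and 6.94) and CST7 (93.4, 12 and 10.7). All of these were among the 10 lowest at 1 uM too. At 0.01 uM 737 loci were higher and 542 lower (468 and 264 protein-coding), and at 1 uM 904 were higher and 558 lower (620 and 257).

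Retinoid metabolism and receptor genes had a median log2 difference of 1.75 at 0.01 uM (percentile 100; 11 of 17 higher, 0 lower) and 2.88 at 1 uM (percentile 100; 13 of 17 higher, 0 lower). TGM2, the tissue transglutaminase, was at 0.06, 78.5 and 322 FPKM, CYP26A1, which degrades RA, at 0.04, 2.49 and 37.4, CYP26B1 at 0.04, 6.21 and 17.6, and RARB at 0.16, 1.07 and 7.51. Granulocyte maturation genes had medians of 1.8 (18 of 30 higher, 2 lower) and 2.15 (18 of 29 higher, 1 lower), both at percentile 100, with CYBB, the oxidase's membrane subunit, at 10.7, 112 and 201, CEBPE at 37.1, 175 and 341, and LYZ lower at 45.3, 10.9 and 13. Interferon genes had 0.67 (7 of 24 higher) and 1.21 (15 of 24 higher), both at percentile 100, with IFI6 at 8.29, 101 and 106. In the primary granule list the medians were 0.62 (percentile 100) and 0.49 (99.98). Its members went both ways: DEFA4 was at 2.18, 271 and 389, BPI at 0.76, 114 and 188, MPO, the myeloperoxidase gene, at 5301, 2678 and 2454, and CTSG, which encodes cathepsin G, at 58.6, 10.3 and 7.01.

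Chemokine and NF-kB genes had medians of 0.14 (percentile 98.29) and 0.78 (100), monocyte and macrophage genes 0.65 (99.98) and 0.95 (99.99), and haemostasis genes -0.22 (11.96) and 0.88 (99.99), with THBD, thrombomodulin, at 1.3, 34.7 and 59.3. MYC targets had -0.23 (0.07) and -0.37 (0), MYC itself being at 319, 135 and 157. Stem and progenitor genes had -0.32 (0.4) and -0.23 (3.41), including TERT, the telomerase reverse transcriptase (16.7, 2.79 and 1.93), and GATA2 (28.5, 12.6 and 14.8). Cell cycle genes had -0.14 (3.78) and -0.17 (1.34) with 1 of 36 higher and 0 lower at each dose. Cholesterol synthesis had -0.18 (4) and -0.11 (16.84), CDK inhibitors 0.01 (75.4) and 0.16 (94.66), apoptosis and stress -0.06 (46.55) and 0.12 (95.03), and LSD1 complex genes -0.08 (35.82) and -0.03 (49.76). Among lists of other cell types, lymphoid genes had 1.28 (99.96) and 1.43 (99.95), led by CD79A (1.62, 50.0 and 55.2), eosinophil, basophil and mast genes -0.36 (2.4) and -0.61 (0.12), megakaryocyte genes 0.44 (98.9) and 0.33 (96.27), and fibroblast and epithelial genes -0.06 (47.86) and 0.03 (60.4).

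The combination was set against DMSO, and held more 2-fold differences than any single treatment: 1252 loci higher and 642 lower, of which 908 and 329 were protein-coding. NCF1 reached 2245 FPKM, ALOX5AP 1091, S100A9 885, S100A8 419.5 (0.92 in DMSO), G0S2 1986 (6.95 in DMSO) and ICAM1, a leukocyte adhesion ligand, 1854 (10.6 in DMSO). The lowest genes were CST7 (4.96 against 93.4), CTSG (4.65 against 58.6), CHAT, KCNH2 (2.32 against 24.5) and DEFB1 (1.12 against 14.1). Granulocyte maturation genes had a median of 2.77 (26 of 33 higher, 0 lower), interferon genes 1.93 (24 of 28 higher), chemokine and NF-kB genes 2.18 (12 of 20), monocyte and macrophage genes 2.12 (13 of 15), retinoid genes 2.39 (13 of 17) and haemostasis genes 1.29 (5 of 10), all at percentile 100 and with 0 members lower. MYC targets had -0.66 (percentile 0; 3 of 26 lower), cholesterol synthesis -0.55 (percentile 0; 6 of 19 lower), cell cycle genes -0.28 (percentile 0.65) and the eosinophil, basophil and mast list -0.82 (percentile 0). HMGCS1 was at 133 against 406 and MYC at 81.3 against 319. Primary granule genes had 0.70 (99.99), CDK inhibitors 0.34 (98.17), lymphoid genes 1.29 (99.91), megakaryocyte genes 0.36 (91.67), apoptosis and stress 0.08 (82.47), LSD1 complex genes 0.05 (78.83), stem and progenitor genes -0.20 (11.92) and fibroblast and epithelial genes -0.31 (18.11).

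**Figure D2:**
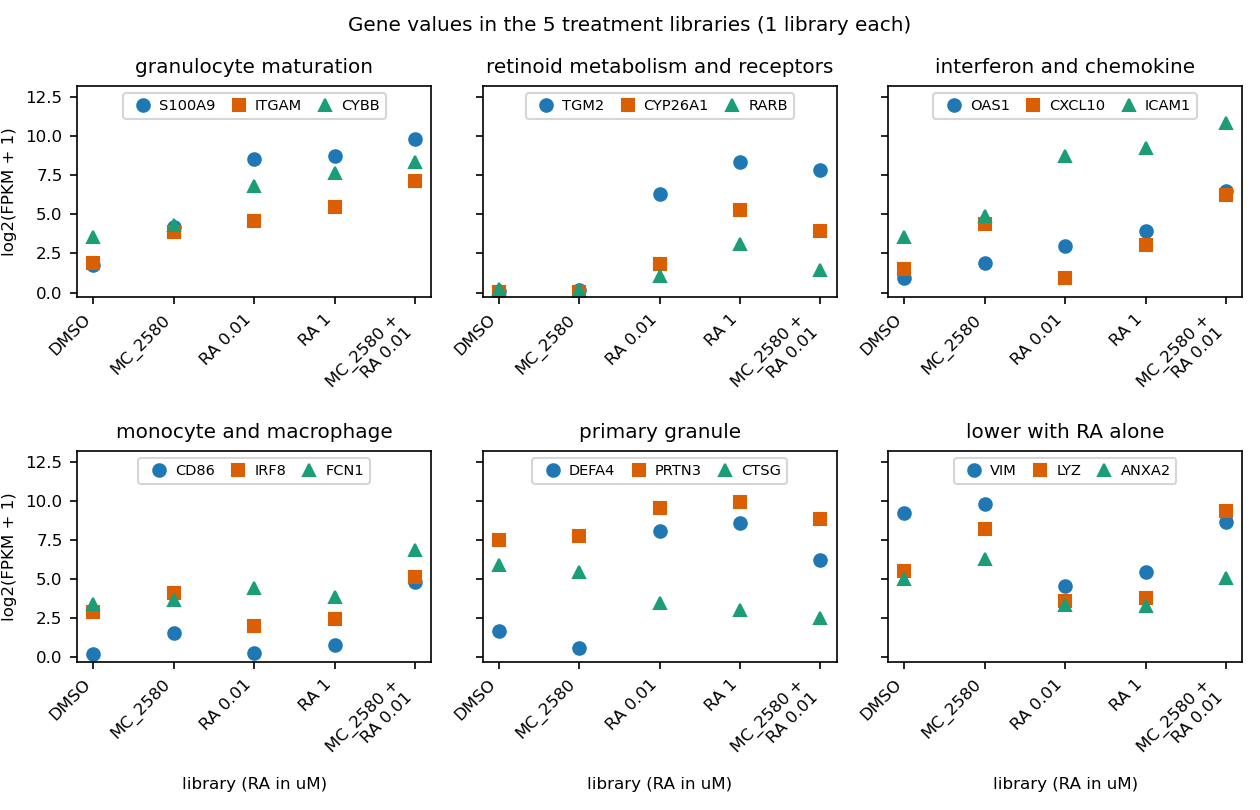
FPKM of 18 genes in the 5 treatment libraries, on a log2(FPKM + 1) axis; each point is 1 library and each panel holds 3 genes. S100A9 goes from 2.44 FPKM in DMSO to 885 in the combination, CD86 is at 27.3 FPKM in the combination and under 2 elsewhere, and VIM is at 22.2 FPKM with RA 0.01 uM and 404 in the combination.

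What the inhibitor added to low-dose RA was read from the combination against RA 0.01 uM. LYZ stood at 653 FPKM in the combination and 10.9 with RA 0.01 uM, CXCL10 at 74.8 and 0.90, CD86, a costimulatory ligand of antigen-presenting cells, at 27.3 and 0.22, LRRK2 at 43.2 and 1.26, GLIPR1 at 34.4 and 0.97, and VIM at 404 and 22.2. PI16 was at 39.6 FPKM and listed at 0 with RA 0.01 uM, RA 1 uM and DMSO. The alpha-defensin genes were lower: DEFA4 was at 72.7 against 271, DEFA1 at 14.5 against 142 and DEFA3 at 178 against 1447, the last pair sharing reads and so uncertain one from the other. Of 13627 loci 689 were higher and 261 lower, and among protein-coding genes 445 and 34. The authors' deposited table calls 483 higher and 102 lower for this pair.

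Monocyte and macrophage genes had the highest median of the lists in this comparison, 1.57 (9 of 16 higher, 0 lower), with FCN1 at 114 against 20.2 and IRF8 at 33.5 against 3.04. Haemostasis genes had 1.25 (5 of 10), chemokine and NF-kB genes 1.15 (14 of 20), interferon genes 1.08 (17 of 28), granulocyte maturation genes 0.77 (16 of 33) and retinoid genes 0.57 (7 of 16), each at percentile 100 with 0 members lower. OAS1, an antiviral enzyme, was at 88.6 against 7.01, IL1B at 24.4 against 2.68, ITGAM at 136 against 22.9 and CYP26A1 at 14.2 against 2.49. Cholesterol synthesis had -0.54 (percentile 0), MYC targets -0.42 (0), primary granule genes -0.27 (0.22; 1 of 17 higher, 4 lower), stem and progenitor genes -0.23 (0.19) and the eosinophil, basophil and mast list -0.18 (1.55). CDK inhibitors had 0.28 (99.08), lymphoid genes 0.36 (97.72), cell cycle genes -0.13 (2.51), apoptosis and stress 0.08 (83.43), LSD1 complex genes -0.02 (42.67), megakaryocyte genes -0.02 (34.57) and the 3 fibroblast and epithelial genes -0.25 (8.39), with a mean of 1.15.

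Against RA at 1 uM, the higher dose, the lowest protein-coding genes in the combination were the alpha-defensin genes DEFA1 (14.5 FPKM against 89.0), DEFA3 (178 against 979) and DEFA4 (72.7 against 389). DEFA1 and DEFA3 share reads, so their values are uncertain. The chemokine gene CCL24 was at 49.7 against 197, RARB was at 1.66 FPKM against 7.51, CYP26B1 at 5.85 against 17.6, CYP26A1 at 14.2 against 37.4, and EPAS1, a hypoxia-inducible factor, at 1.66 against 11.2. LYZ was at 653 against 13, CLEC4A at 19.5 against 0.04, CD86 at 27.3 against 0.74, HP, haptoglobin, at 15.9 against 0.43, and CD48 at 42.3 against 3.04. Retinoid genes had a median of -0.22 (percentile 0.17; 1 of 17 higher, 3 lower), and this median was 0.01 without the filter on low values. Monocyte and macrophage genes had 1.16 (9 of 15 higher), chemokine and NF-kB genes 1.03 (10 of 20 higher, 1 lower), granulocyte maturation genes 0.75 (13 of 32) and interferon genes 0.70 (10 of 28), all at percentile 100. Between WT 1 and WT 2 the chemokine and NF-kB median was 0.99 and the interferon median 0.79, so these values do not stand clear of a same-group difference. In all, 553 loci were higher and 250 lower (5.9%), 324 and 45 of them protein-coding (3.9%). Neither share stood clear of those between libraries of 1 group in the knockout table. Those come from another set, and MC_2580 against DMSO marked only 0.8% of protein-coding genes. How much the treatment libraries differ without a treatment is unknown, so this comparison decides little.

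Of the remaining lists in that comparison, haemostasis genes had 0.53 (99.98), CDK inhibitors 0.29 (99.88) and lymphoid genes 0.49 (99.77). Cholesterol synthesis had -0.39 (0), MYC targets -0.31 (0), cell cycle genes -0.24 (0), the eosinophil, basophil and mast list -0.25 (0.59), primary granule genes -0.22 (0.52) and fibroblast and epithelial genes -0.35 (1.04), the last with a mean of 0.40. Apoptosis and stress had 0.04 (85.86), LSD1 complex genes 0.01 (81.29), stem and progenitor genes -0.10 (10.55) and megakaryocyte genes -0.01 (50.88).

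**Figure D3:**
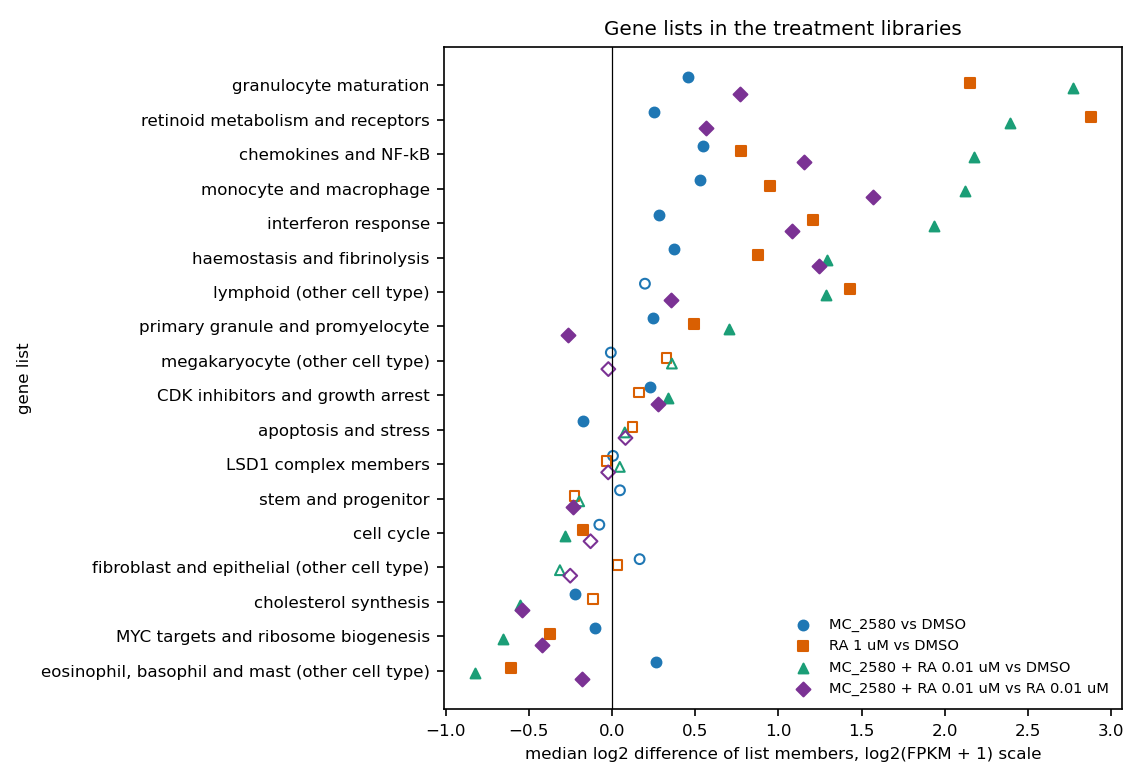
Median log2 difference of each gene list's members in 4 treatment comparisons, on the log2(FPKM + 1) scale; filled symbols lie in the lowest or highest 2.5% of 10000 matched random lists and open symbols between. Granulocyte maturation reaches 2.77 for the combination against DMSO, and primary granule genes lie at 0.25 for MC_2580 against DMSO and -0.27 for the combination against RA 0.01 uM.

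The combination was also compared with the sum of the log2 differences of its single treatments. LILRA5, a leukocyte receptor, exceeded the sum by 3.59 (54.7 FPKM in the combination, 3.55 with RA 0.01 uM, 0.03 with MC_2580), HP by 3.57, VIM by 3.56, ADGRE3 (EMR3 in the table) by 3.23, CD86 by 3.21 and LYZ by 3.13. DEFA1 lay below the sum at -3.45 and DEFA3 at -2.03, followed by PHACTR3 (-1.64) and PWWP2B (-1.57). Of 14045 loci 635 lay at least 1 log2 unit above the sum and 383 below, and among protein-coding genes 276 and 34. Interferon genes had a median excess of 1.01 (14 of 28 above, 0 below), monocyte and macrophage genes 0.90 (6 of 15), chemokine and NF-kB genes 0.88 (8 of 20) and granulocyte maturation genes 0.41 (9 of 33, with 1 below), all at percentile 100. Haemostasis genes had 0.53 (99.98) and retinoid genes 0.44 (99.99). Primary granule genes lay below the sum (-0.58, percentile 0), as did MYC targets (-0.33, 0), cholesterol synthesis (-0.23, 0.25) and cell cycle genes (-0.19, 0.12). Apoptosis and stress had 0.15 (97.9), CDK inhibitors 0.07 (54.72), LSD1 complex genes 0.06 (81.31), lymphoid genes 0.01 (40.16), megakaryocyte genes 0.03 (41.36), erythroid genes 0.13 (49.28), stem and progenitor genes -0.06 (17.32), the eosinophil, basophil and mast list -0.07 (13.42) and fibroblast and epithelial genes -0.10 (19.96, with a mean of 0.70).

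How far the combination resembled the higher RA dose was measured by overlap. Among loci measured in both comparisons, 684 of 783 that were higher with RA 1 uM than DMSO were also higher with the combination (87.4%), NCF1, TGM2 and S100A9 among them, and 370 of 557 lower loci were also lower (66.4%), CTSG and TERT among them. With RA 0.01 uM the shares were 70.3% and 75.1%, and with MC_2580 12% and 29.2%. Because the DMSO library is shared, unchanged libraries simulated from replicate noise share 40.8% and 40.3%, and independent lists would share 61.6 and 26.6 loci. The noise drawn from the knockout table gave 757.57 higher loci in unchanged libraries, where MC_2580 had 178. The simulated shares are therefore a rough baseline for these libraries. Over protein-coding genes the combination shared 541 of 605 higher genes (89.4%; simulated 22.9%, independent 52.7 genes) and 167 of 257 lower genes (65.0%; simulated 22.2%, independent 8.9 genes). The covariance of their log2 differences across these genes was 0.563 (r = 0.884) against 0.111 simulated. RA 0.01 uM alone shared 71.1% of the higher and 82.0% of the lower protein-coding genes with a covariance of 0.478 (r = 0.953), so by r and by lower genes it lay closer to RA 1 uM than the combination did. With 1 DMSO library the controls cannot be split, so part of the excess may come from sharing it.

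The KO and the inhibitor were compared across 9593 genes measured in both tables, which share no library. Of the called genes over all loci, CLEC5A and RTN4RL2 rose in KO cells and RTN4RL2 was 2-fold higher with MC_2580. CLEC5A was also higher (0.68 FPKM in DMSO and 2.11 with MC_2580) but missed 2-fold on the FPKM + 1 scale (log2 difference 0.89). PXDN (13.9 FPKM in DMSO and 14.4 with MC_2580) and DEFB1 (14.1 and 9.02), which fell in KO cells, were not 2-fold lower. Of the 29 genes that rose in the fit over protein-coding genes and were measured here, 13 (44.8%) were 2-fold higher with MC_2580, where independent lists would share 0.25, and 28 had the same sign. In both directions the overlap was 1 of 4 (25.0%) for calls over all loci and 14 of 45 (31.1%) for calls over protein-coding genes. S100A8, S100A9, TMEM243 (C7orf23) and RTN4RL2 were among the 13. Of 16 genes that fell, 1 was 2-fold lower with MC_2580, DEFA4, and 9 had the same sign. Across genes, which are not independent replicates, the log2 differences of KO and MC_2580 had a Pearson r of 0.15 and a Spearman rho of 0.191. Against the combination relative to RA 0.01 uM these were 0.305 and 0.279, and against RA 1 uM -0.004 and 0.032.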

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

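The test of shared reads and the comparison with libraries of 1 group below were chosen only after the results were seen. Among the lists, primary granule and promyelocyte genes and eosinophil, basophil and mast genes had a median effect of MC_2580 in the highest 2.5% of matched random lists without RA and in the lowest 2.5% with RA. Medians of other lists also differed in sign without reaching both ends, among them apoptosis and stress (-0.17 without RA, 0.08 with RA), stem and progenitor (0.05 and -0.23), and fibroblast and epithelial genes (0.17 and -0.25). For the primary granule list the median log2 effect of MC_2580 was 0.248 without RA and -0.266 with RA 0.01 uM; the difference was not tested, since each group is 1 library. DEFA4 (271 FPKM with RA 0.01 uM, 72.7 with the combination), PRTN3 (762 and 454) and CTSG (10.3 and 4.65) were lower in the combination, while SERPINB10 (0.0739 and 3.16) was higher and MPO (2678 and 2873) differed little. Without DEFA1 and DEFA3, which share reads, the median was -0.172. In size this lies below the -0.191 of this list between WT 1 and WT 2, so shared reads are not excluded as an explanation. No separate test of the scaling of the combination library was run. Between libraries of 1 group in the knockout table the median of this list was -0.191 (WT 1 against WT 2) and 0.106 (KO 1 against KO 2), so the difference from variation between single libraries is small. An effect of the inhibitor on these genes in the presence of RA stays open, untested with 1 library per group. For the eosinophil, basophil and mast list the medians were 0.262 and -0.183, also not tested, and -0.176 and -0.157 between libraries of 1 group.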

How the results depend on the processing

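The restriction to protein-coding genes with 1 locus, alone or with the replicate block, was chosen only after the results were seen, as were other filters, a pseudocount of 5 and quantile normalization for gene lists. For KO against WT the 15 calls of limma became 38 with a pseudocount of 0.1, 0 with 5 (926 at an unadjusted p under 0.05), 0 without a filter (1720), 7 with a filter of 5 FPKM, 59 among protein-coding genes, and 0 without any 1 library (range 0 to 0; 654 to 801 at an unadjusted p under 0.05). Treating the replicate numbers as pairs (the labels do not say what a number marks; the replicate differences correlate at 0.21 across genes) gave 0 calls over all loci (3198 at an unadjusted p under 0.05) and 2903 among protein-coding genes, where 16 of 20 cholesterol synthesis genes (17 adjusted over the list alone) and KDM1A (-1.84, adjusted p = 2.09e-06) also passed; over all loci it lost the call of the fibroblast and epithelial list (adjusted p = 0.129) and added cell cycle (0.0431). For KDM1A the log2 difference without 1 library ran from -2.05 to -1.64. Called gene lists numbered 0 with an estimated correlation and 4 to 7 without 1 library. The chemokine and NF-kB call was lost with quantile normalization (adjusted p = 0.055) and a filter of 5 FPKM (0.203), the fibroblast and epithelial call without a filter (0.378) and with a filter of 5 FPKM (0.0572), and the eosinophil, basophil and mast list was called without a filter (0.0227) and with a filter of 5 FPKM (0.0133). Among protein-coding genes the haemostasis and the monocyte and macrophage lists were called too (0.0499 each). The median of the chemokine and NF-kB list ran from -0.948 without WT replicate 2 to 0.069 without WT replicate 1, and was 0.057 without KO replicate 2. Without 1 library the medians of other lists also took both signs, from -0.466 to 0.155 for cell cycle, -0.47 to 0.16 for MYC targets, -0.615 to 0.213 for interferon response, -0.214 to 0.402 for retinoid genes, -0.344 to 0.259 for megakaryocyte genes, -0.137 to 0.044 for CDK inhibitors, -0.173 to 0.091 for apoptosis and stress, -0.009 to 0.058 for LSD1 complex members and -0.035 to 0.059 for stem and progenitor genes. For chemokine, cell cycle, MYC target and interferon genes, replicate 1 differed from replicate 2 in the same direction in KO and in WT. Without 1 library this difference is no longer balanced between the groups. At 4-fold the loci higher or lower numbered 325 for MC_2580, 529 for RA 0.01 uM, 564 for RA 1 uM and 726 for the combination against DMSO, and 411 and 361 for the combination against RA 0.01 uM and RA 1 uM. A pseudocount of 5 gave 756, 856, 1081, 553 and 477 for the last 5 of these and 674 against the sum. Protein-coding genes alone gave 71, 732, 877, 1237, 479 and 369, and 310 against the sum. The authors' deposited calls gave 220 for MC_2580, 585 for the combination against RA 0.01 uM and 479 against RA 1 uM. The overlap of KO calls with MC_2580 over all loci and over protein-coding genes was 50.0% and 44.4% with a pseudocount of 0.1, 75.0% and 53.3% at 1.5-fold and 33.3% and 29.2% with a filter of 5 FPKM. For the combination against RA 1 uM, the fibroblast and epithelial list turned to 0.402 by its mean and the retinoid list to 0.007 without a filter. Fewer or other loci enter under a filter, a higher threshold or protein-coding genes alone; for the rest the cause was not tested. Over all alternatives 66 summary values stayed within their limits, 35 moved beyond them and 1 newly passed. Of the values for single genes and lists, 363 in the knockout comparison kept their sign and call, 53 newly passed and 54 no longer passed. In all 18 were counted as changed in sign. No limit was set for single genes and list medians of the treatments. The other 895 values are theirs, counted without regard to how far they moved. The erythroid list had no member left with a filter of 5 FPKM. Alternatives that need counts, or a table holding only the authors' comparison, were not run. Without read totals the depth behind low values is unknown.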

Other observations

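The tests in this part were all chosen only after the results were seen. Genes lower with RA were in part higher when MC_2580 was added to RA, but so were genes higher with RA. Of 216 protein-coding genes 2-fold lower at RA 1 uM than in DMSO, 37 (17.1%) were 2-fold higher in the combination than with RA 0.01 uM, where independent lists would share 8.7, and 12 were lower (0.8). These libraries are not shared between the comparisons. VIM went from 593 FPKM in DMSO to 42.7 with RA 1 uM and from 22.2 with RA 0.01 uM to 404 in the combination, and STAB1, a scavenger receptor, stood at 12.5, 0.272, 0.188 and 5.4 in the same order (DMSO, RA 1 uM, RA 0.01 uM, combination). ANXA2, a plasminogen-binding annexin, stood at 31.9, 8.84, 9.15 and 33.3 in that order. Of 608 genes higher at RA 1 uM, 130 (21.4%) were also higher in the combination than with RA 0.01 uM (24.4 for independent lists), and 5 were lower (2.2). A rise with added MC_2580 was thus not particular to genes lower with RA.

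GFI1 and GFI1B, repressors that recruit LSD1, were highest in the combination among the treatment libraries. GFI1 stood at 67.1 FPKM in DMSO, 106 with MC_2580, 41.4 with RA 0.01 uM, 55.3 with RA 1 uM and 167 in the combination, and GFI1B at 1.87, 6.71, 22.9, 8.83 and 95.4. In the knockout set GFI1 was at 98.4 and 98.2 against 43.7 and 46.5 in WT, and GFI1B at 7.16 and 6.07 against 4.52 and 1.39.

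The loci other than protein-coding genes among the knockout calls may rest on a few reads. All 11 were listed at 0 in 1 group, and in 11 the ratio of the other group's libraries matched, within 1%, that of 1 to 4 reads in each, against 8.9% of protein-coding genes of at least 5 FPKM. No biological explanation was tested for these loci.

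CD3G, CD2 and CD79A were higher in KO than in WT cells. T cells among the KO cells are argued against by CD3E, CD7, IL7R, LEF1 and TCF7, none above 0.227 FPKM in a KO library, while CD3G stood at 12.9 and 13.6. Other genes of lymphoid cells were higher in KO cells too, GZMA (4.53 and 4.05 against 0 and 0), GIMAP4 (3.59 and 3.82 against 0 and 0) and CD3D (213 and 173 against 115 and 69.0), but T cells would bring CD3E as well, which stood at 0.0267 and 0.0824. B cells are argued against by MS4A1, PAX5 and IGJ, none above 0.043 FPKM, while CD79A stood at 7.87 and 8.77. Of the 3 genes, 0 were 2-fold higher with MC_2580, but CD2 (0.0606 FPKM in DMSO and 0.0864 with MC_2580) and CD3G (0.418 and 0.239) lay under 1 FPKM in both libraries, so this test decides little. GIMAP4, outside that test, was higher in the combination than with RA 1 uM (log2 difference 3.35). In the same 2 libraries CD3G stayed low (0.214 in the combination and 0.191 with RA 1 uM), and CD79A stood at 73.4 and 55.2. A difference between the lines other than loss of LSD1 cannot be told apart from loss of LSD1, since the labels do not say how many KO clones the libraries came from. An effect of LSD1 loss on these genes may remain as an untested hypothesis.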
